A study of Homo sapiens with 6 samples.

How the data were processed

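RNA was measured in 6 libraries of the T-ALL line DND41, 3 of the washout and 3 of the mock washout group, as the sample titles and the treatment label name them. Per the labels' protocols, 800 ng of total RNA with integrity numbers above 9.5 went into a SMARTer total RNA library kit, and single-end reads of 75 bp were sequenced on an Illumina NextSeq instrument.

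The deposited values are raw read counts per gene, 1 table per library. Per the file headers, the authors counted reads with featureCounts 1.5.1 over exons, summed per gene and with strand setting 1 (same strand), on an Ensembl release 75 annotation of GRCh37 whose name says that ribosomal RNA and mitochondrial genes were removed. No option for reads with several alignments or for reads overlapping several genes is set in those headers, so such reads do not enter the counts, which lowers genes with near-identical copies or same-strand overlaps. Per the submitters' processing notes, STAR 2.5, Subread 1.5.1 and featureCounts were used with GRCh37 (hg19). The filter applied to the alignments before counting is not given in the sources used here. The tables also hold each gene's summed exon length in bases, per the file headers, which served only for the checks of gene length. Coordinates are those of the deposited tables.

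Of 57209 gene identifiers, 38994 were named from a table of current symbols, 12795 from GENCODE 29 and 5420 have no symbol. GENCODE 29 belongs to another build and served only for names, gene types, GC content and the length of the main transcript. Total counts per library ranged from 26324502 to 33845848, and 99.9% of them fell in the 14168 genes tested. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom between 4.68 and 40), so each was counted as 1 sample.

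Genes were filtered with filterByExpr, libraries were scaled with TMM factors, and washout was compared with mock washout by the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, in which the older of the fits is the default, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. Levels per group are CPM on TMM-scaled library sizes, as mean ± SD. The biological coefficient of variation was 7.14%. Tools besides edgeR were limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

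The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 27 lists held 646 entries, of which 614 matched an identifier in the tables. They cover Notch targets, Notch pathway components, ribosome biogenesis, cytosolic ribosomal proteins, snoRNA host transcripts, nucleotide synthesis, one-carbon and polyamine metabolism, aminoacyl-tRNA synthetases, the ATF4 response, glycolysis, cholesterol, G1/S, G2/M, T-cell genes, FOXO targets, NF-kappaB targets, interferon-stimulated genes, p53 targets, immediate early genes, heat shock, structural RNAs, histones, mitochondrial mRNAs, and B-cell, breast epithelial, myeloid and stromal markers. Lists with at least 5 genes tested, 22 in all, were tested with camera at a preset correlation of 0.01, adjusted over those lists, and again with an estimated correlation and with fry.

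The text names every tested Notch target, the 12 largest rises and the 12 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between groups, up to 4 called members with the smallest adjusted p of each list that passed, in its direction, and up to 2 of each list that did not pass. Some genes that meet this rule are not reported here. Neighbouring genes were counted as pairs of called genes on a chromosome with a gap of at most 100 kb, against 10000 draws matched on 10 classes of mean expression.

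Alternatives were DESeq2 size factors, library totals only, upper-quartile factors, DESeq2, limma-voom, no abundance filter, a CPM of at least 1 in 3 libraries, the replicate number as a block, offsets for gene length, both together, structural RNAs left out, a threshold of 0.01, and each library left out. Added after the data were seen were the newer edgeR fit, the 20 most abundant genes left out, offsets for GC content and for transcript length, only genes of at least 2500 exonic bases, and 5 further counts of neighbouring pairs.

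The steps were tested on data simulated from the libraries' means and depths. Each simulation of the fit changed far fewer genes than were called in the data, so its rates need not hold there. In 5 simulations of washout against mock washout over 13991 genes, the fit recovered 32% of genes changed 1.25-fold, 70.6% of those changed 1.5-fold, 84.6% of those changed 2-fold and 98.8% of those changed 4-fold, and 9.35% of its calls were unchanged genes, above the nominal 5%. A list raised 1.25-fold was called at an adjusted p of 6.88e-90 by camera, and 0 unchanged lists were called. This was 1 run with genes drawn independently of each other, so it cannot show how camera treats lists of correlated genes. Over 14168 genes, the pair count passed 0.05 for 1 of 20 random sets and gave a ratio of 2.19 with 200 planted pairs. That ratio is far above the 1.3 found in the data, so it cannot show how well smaller ratios are detected.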

Results

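RNA of DND41 cells, a human line of T-cell acute lymphoblastic leukaemia (T-ALL), was sequenced in 6 libraries that form 2 groups of 3. All cells had spent 72 h in 1 µM of compound E, a gamma-secretase inhibitor that blocks the cleavage by which Notch receptors are activated. After a wash they were grown for 5 h more, either with the vehicle (washout, Notch signalling released) or with 1 µM inhibitor again (mock washout, Notch signalling still blocked). The comparison asks which transcripts differ within hours of the inhibitor's removal. Counts assigned to genes totalled 28708806, 30865300 and 26324502 in washout libraries 1, 2 and 3, and 28066084, 28686486 and 33845848 in mock washout libraries 1, 2 and 3. Of 57209 annotated genes, 14168 held enough counts to be tested. The labels number the replicates without saying that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Changes below are log2 fold changes of washout over mock washout, written ± SE and estimated from 3 libraries per group, and levels are CPM (a gene's counts relative to the scaled library total) as mean ± SD. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and those of gene lists from camera.

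The known target genes of Notch in T-ALL were higher in washout: 10 of the 12 that could be tested rose and 1 fell, with a median change of 0.74. NOTCH3, a receptor gene that Notch itself activates (chromosome 19, 15270444 to 15311792, GRCh37), rose from 15.4 ± 0.597 to 92.1 ± 11.1 CPM. MYC, a transcription factor gene that drives cell growth (chromosome 8, 128747680 to 128753674), rose from 44.6 ± 0.695 to 153 ± 7.67 CPM. The changes were 2.58 ± 0.0895 for NOTCH3 and 1.78 ± 0.0562 for MYC, with edgeR adjusted p-values of 7.9e-08 and 5.95e-08. CR2, a complement receptor gene, had the largest change of the list at 3.12 ± 0.257 but a low level of 2.02 ± 0.0438 against 0.229 ± 0.0406 CPM (edgeR adjusted p = 4.72e-05). DTX1, a Notch-induced ubiquitin ligase gene, rose by 1.53 ± 0.0712 and LZTFL1, a regulator of ciliary protein traffic, by 1.37 ± 0.0698 (edgeR adjusted p = 8.6e-07 and 1.85e-06). NOTCH1, the receptor gene mutated in many T-ALLs, rose by 0.81 ± 0.0658 and SHQ1, an assembly factor of small nucleolar ribonucleoproteins, by 0.67 ± 0.0589 (edgeR adjusted p = 4.48e-05 and 7.53e-05). HES1, the transcriptional repressor gene commonly used as a readout of Notch, rose by 0.43 ± 0.0538, from 153 ± 1.99 to 207 ± 10.1 CPM (edgeR adjusted p = 0.000655). Smaller rises were those of IGF1R, a growth factor receptor gene, at 0.29 ± 0.0566 and IL7R, a cytokine receptor gene, at 0.24 ± 0.0624 (edgeR adjusted p = 0.0081 and 0.0223). CCND3, which encodes a D-type cyclin, fell by 0.18 on the log2 scale (SE 0.0555, edgeR adjusted p = 0.0405), and TRIB2, a pseudokinase gene, had a value of -0.11 ± 0.0566 that did not pass (edgeR adjusted p = 0.199). Each of the 10 genes that rose was higher in all 3 washout libraries than in any mock washout library. The other 8 members were not tested because they held few or no counts: HEY1 reached 11 in a library, HES4 4, HES5 2, and NRARP and PTCRA 1 each, while HEY2, HEYL and FJX1 held none.

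Across the 12 genes, camera gave an adjusted p of 9.52e-45, and an adjusted p = 0.0223 with an estimated correlation between genes. Adjusted over the list alone, the counts of 10 higher and 1 lower were the same. IL7R and CCND3 lost their calls without washout library 2 or without any 1 of the mock washout libraries (highest edgeR adjusted p = 0.0939 and 0.141), and IGF1R without mock washout library 1 (0.058). IL7R also lost its call when libraries were scaled by their totals only (edgeR adjusted p = 0.0732).

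**Figure D1:**
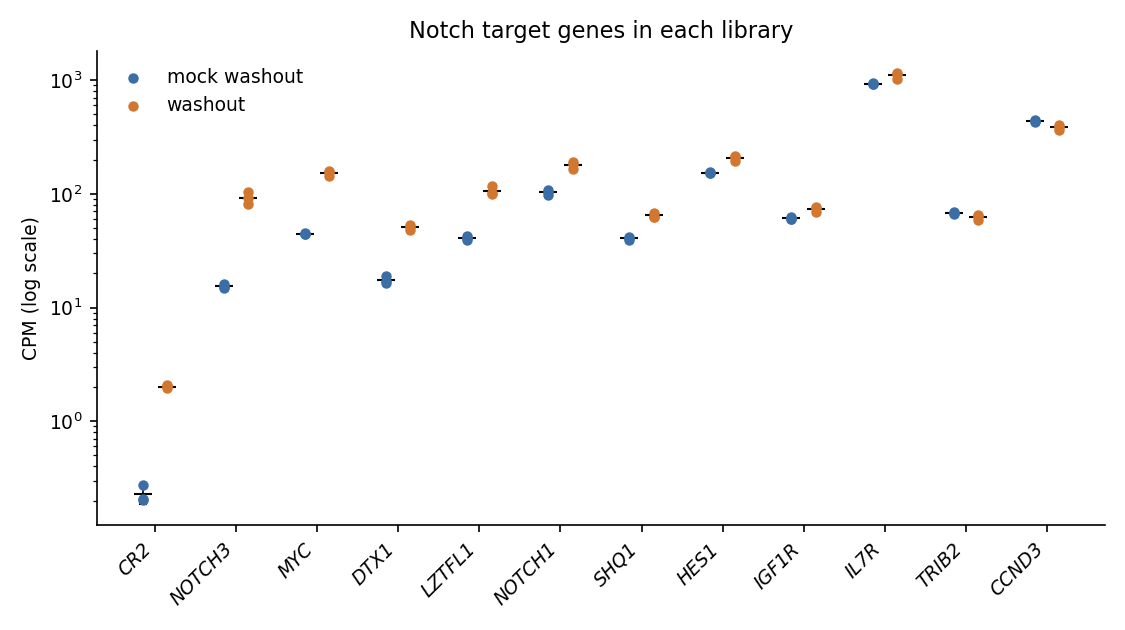
Level of each tested Notch target gene in each library, in CPM on a log scale, with one point per library and black bars for the mean and SD of the 3 libraries of a group (orange washout, blue mock washout). NOTCH3, MYC, DTX1, LZTFL1 and CR2 are more than 2-fold apart between the groups, while CCND3 and TRIB2 lie slightly lower in washout.

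Over all genes tested, 1623 were higher and 1392 lower in washout at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). Most changes were small: the median size among the 3015 called genes was 0.35 on the log2 scale, and 198 changed at least 2-fold, 188 of them higher and 10 lower. Scaling by library totals only turned the split of called genes to 1328 higher and 2015 lower, so that 39.7% in place of 53.8% were higher. In 2919 genes all 3 washout libraries lay above all 3 mock washout libraries and in 2938 all lay below, where chance alone gives 10% of genes for both directions together. Leaving out a library changed the number called to 4600 without washout 1, 1367 without washout 2, 2908 without washout 3, 791 without mock washout 1, 1243 without mock washout 2 and 984 without mock washout 3. In simulations of this comparison 9.35% of calls were unchanged genes, but those simulations changed far fewer genes than the 3015 called here. The share of unchanged genes among the 3015 was not measured. The genes called at least 2-fold numbered 354, 146, 128, 87, 114 and 109 with those libraries left out in the same order. On the first principal component, which held 53.8% of the variance, washout library 3 stood apart at -38.1, with washout libraries 1 and 2 at -5.77 and -13.8 and mock washout libraries 1 to 3 at 21.7, 19.6 and 16.3.

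**Figure D2:**
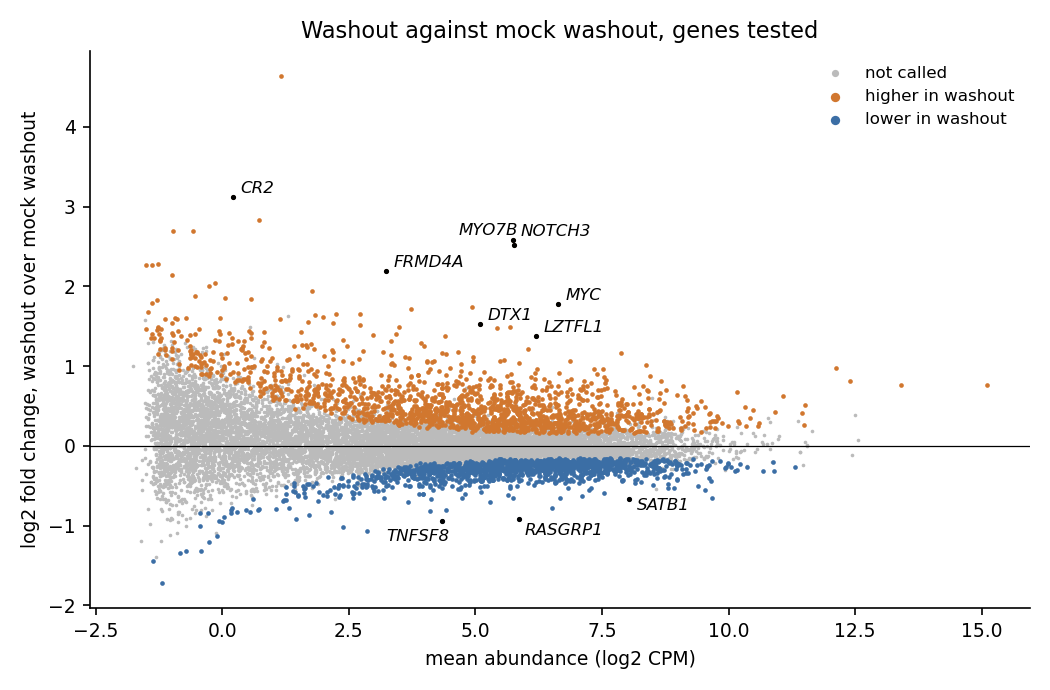
Change of each of the 14168 genes tested, as log2 fold change of washout over mock washout (vertical) against its mean abundance in log2 CPM (horizontal), with genes called higher in orange, called lower in blue and the rest in grey. Among called genes with a mean log2 CPM of at least 3, NOTCH3, MYO7B and FRMD4A lie highest at 2.58, 2.52 and 2.19, followed by MYC at 1.78 and GIMAP5 at 1.74, and TNFSF8 and RASGRP1, the largest falls among named genes of that abundance, are under 2-fold.

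Among genes of at least moderate abundance, the largest rises besides NOTCH3, MYC, DTX1 and LZTFL1 were those of MYO7B, FRMD4A and GIMAP5. MYO7B, an unconventional myosin gene (chromosome 2, 128293378 to 128395304, GRCh37), rose by 2.52 ± 0.082, from 16.1 ± 1.44 to 92.4 ± 7.03 CPM (edgeR adjusted p = 5.95e-08). FRMD4A, a scaffold gene of cell polarity, rose by 2.19 ± 0.0964, and GIMAP5, which encodes a GTPase of lymphocytes, by 1.74 ± 0.0777 (edgeR adjusted p = 6.84e-07 for both). For GIMAP5, 6.9% of the exonic bases overlap another gene of the same strand. GIMAP7, of the same GTPase family, rose by 1.47 ± 0.124 (edgeR adjusted p = 4.93e-05). NOP16, a ribosome assembly factor, rose by 1.49 ± 0.228, and POLR1G, a subunit gene of RNA polymerase I, by 1.40 ± 0.158 (edgeR adjusted p = 0.00237 and 0.000336). SCARNA21, a small RNA of Cajal bodies, and RPS27, a ribosomal protein gene, had changes of 1.72 ± 0.448 and 1.49 ± 0.377 that rested largely on washout library 3. SCARNA21 stood at 8.33, 14.2 and 39.3 CPM in the washout libraries against a mock washout mean of 6.22 ± 0.172, and RPS27 at 37.5, 55.7 and 137 CPM against 27.1 ± 5.42. Their edgeR adjusted p-values were 0.0238 and 0.0212. Without washout library 3 the changes were 0.86 and 0.78, and both calls were lost without any 1 of the mock washout libraries (highest edgeR adjusted p = 0.0941 and 0.101). SCARNA21 also missed the threshold in limma-voom (adjusted p = 0.0666) and RPS27 in DESeq2 (adjusted p = 0.0511).

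Among called genes with a mean log2 CPM of at least 3 and groups that did not overlap, the largest falls were smaller in size than the largest rises. TNFSF8, which encodes the CD30 ligand (chromosome 9, 117656003 to 117692697, GRCh37), fell from 26.3 ± 1.14 to 13.7 ± 1.1 CPM, a change of -0.94 ± 0.0785. RASGRP1, a Ras activator downstream of the T-cell receptor, fell from 76.1 ± 0.26 to 40.1 ± 3.3 CPM, a change of -0.92 ± 0.0651 (edgeR adjusted p = 4.9e-05 for TNFSF8 and 2.04e-05 for RASGRP1). PRDM1, a transcriptional repressor of lymphocyte differentiation, changed by -0.82, the cytokine gene CSF1 by -0.80 and the amino acid transporter gene SLC43A2 by -0.78. Further falls were those of the non-coding LINC02273 (-0.71), of EVI2B (-0.71), of the endoplasmic reticulum turnover receptor RETREG1 (-0.67) and of the chromatin organiser SATB1 (-0.66 ± 0.0539). The kinase gene PIM2, the phosphoinositide 3-kinase subunit gene PIK3R5 and the glycoprotein degradation gene EDEM1 each changed by -0.66. The edgeR adjusted p-values of these 10 genes lay between 4.48e-05 for SATB1 and 0.00517 for PIM2, and in each the 3 washout values lay below the 3 mock washout values. For EVI2B, 30.1% of the exonic bases overlap another gene of the same strand, so its level is uncertain.

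Many genes of ribosome production were higher in washout. Of 45 tested genes of ribosome biogenesis, 41 rose and 0 fell, with a median change of 0.62 and an adjusted p of 1.36e-47 by camera (adjusted p = 0.0362 with an estimated correlation). Examples are GNL3, a nucleolar GTPase gene, at 0.96 ± 0.07, RRS1 at 1.15 ± 0.0869, MRTO4 at 0.83 ± 0.0612 and MYBBP1A at 0.73 ± 0.0545, with edgeR adjusted p-values from 2.5e-05 to 3.39e-05. Of the transcripts that host small nucleolar RNAs in their introns, 16 of 16 rose, with a median of 0.62 (camera adjusted p = 7.19e-17). This call was lost at an adjusted p = 0.134 with an estimated correlation. SNHG15 rose by 1.02 ± 0.0855, SNHG3 by 0.89 ± 0.122, SNHG16 by 0.74 ± 0.0675 and TAF1D by 0.60 ± 0.0738 (edgeR adjusted p between 4.9e-05 and 0.00128). Of 74 tested genes of cytosolic ribosomal proteins, 42 rose and 0 fell, with a median of 0.25 (camera adjusted p = 1.97e-09), a call lost at an adjusted p = 0.263 with an estimated correlation. RPL27 rose by 0.75 ± 0.138, RPL12 by 0.70 ± 0.133 and RPLP1 by 0.62 ± 0.109 (edgeR adjusted p between 0.00459 and 0.00704). Of 8 abundant structural RNAs, 5 rose with a median of 0.62 (camera adjusted p = 0.00031), also lost at an adjusted p = 0.134 with an estimated correlation. They were RMRP at 0.87 ± 0.142, SCARNA7 at 0.70 ± 0.143, RNU4ATAC at 0.69 ± 0.138, the telomerase RNA TERC at 0.54 ± 0.117 (edgeR adjusted p between 0.00325 and 0.0116), and MALAT1, named after its value was seen. Adjusted over the list alone, 42 biogenesis genes, 16 host transcripts, 49 ribosomal protein genes and 6 structural RNAs were higher, and 1 ribosomal protein gene was lower. Parts of the exons of RRS1 (11.4%), TAF1D (11.2%), SNHG3 (5.92%) and GNL3 (3.65%) overlap another gene of the same strand, so these levels are less certain.

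Short transcripts were higher in washout as a class, and most of all in washout library 3. Among 679 tested genes with a main transcript under 500 bases, 117 rose and 5 fell, with a median change of 0.36. Their median deviation from the mean of all libraries was 0.08, 0.11 and 0.38 in washout libraries 1 to 3 and -0.15, -0.15 and -0.20 in mock washout libraries 1 to 3. The gene ENSG00000202198, which carries no symbol here, took 3.93%, 4.13% and 4.98% of the counts in the washout libraries and 2.71%, 2.80% and 2.47% in the mock washout libraries. It was not matched to the structural RNA list, in which 8 of 13 members were matched. The run without structural RNAs therefore kept it. The shares of MALAT1 were 1.07%, 1.16% and 1.78% against 0.808%, 0.759% and 0.901%. The median transcript length was 886 bases for the ribosomal protein genes, 760.5 for the host transcripts and 330 for the structural RNAs, against 2588 for the biogenesis genes. With offsets that remove each library's trend on transcript length, the medians were 0.65 for biogenesis, 0.44 for host transcripts, 0.10 for ribosomal protein genes and 0.27 for structural RNAs, with camera adjusted p-values of 2.38e-52, 2.18e-13, 0.00263 and 0.0421. Without washout library 3 the medians of ribosomal protein genes and structural RNAs were 0.20 and 0.42. RNU4ATAC lost its call with those offsets (edgeR adjusted p = 0.44), and single calls were lost without mock washout library 1 for SCARNA7 and RPL12 (0.0611 and 0.0516) and without mock washout library 2 or 3 for TERC (up to 0.0629). The number of ribosomal protein genes that rose was 21 without washout library 2 and 4, 23 and 7 without mock washout libraries 1, 2 and 3. Host transcripts that rose numbered 10 without mock washout library 1, and structural RNAs 3 without mock washout library 1 or 2. Ribosomal protein genes have many near-identical pseudogenes, so their levels are uncertain.

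**Figure D3:**
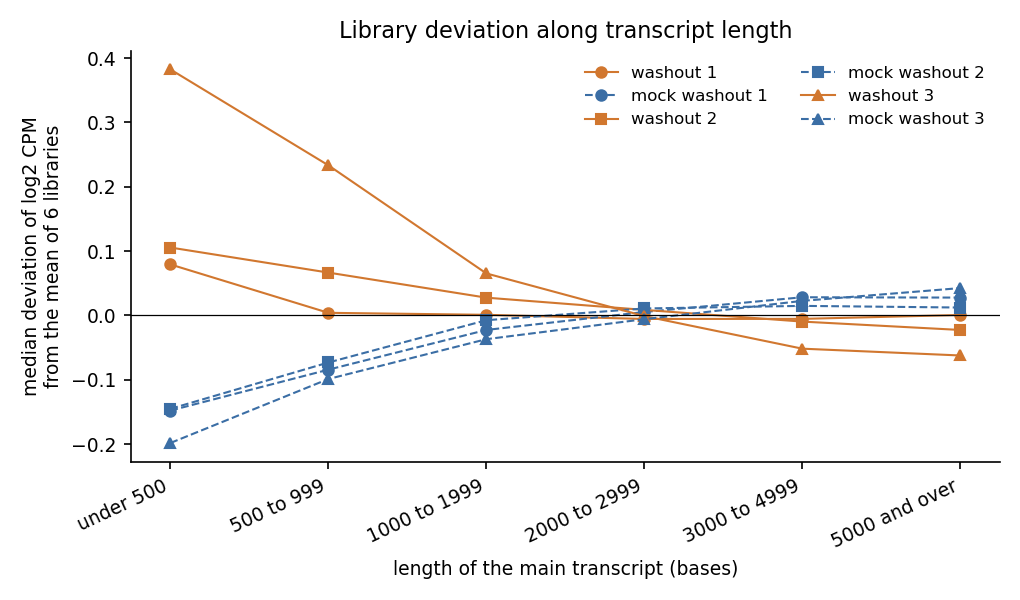
Median deviation of each library from the mean of the 6 libraries (log2 CPM, vertical) for tested genes in 6 classes of main transcript length in bases (horizontal), with one line per library. Washout library 3 stands highest for transcripts under 500 bases at 0.38, and the 3 mock washout libraries lie between -0.15 and -0.20.

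Several metabolic and chaperone lists were higher in washout by smaller amounts. Of 24 genes of nucleotide synthesis, 11 rose and 1 fell, with a median of 0.19 (camera adjusted p = 0.00607), not past the threshold at an adjusted p = 0.182 with an estimated correlation. NME2, a nucleoside diphosphate kinase gene, rose by 0.75 ± 0.102, DHODH, a pyrimidine synthesis enzyme gene, by 0.72 ± 0.0947, and the purine synthesis genes PFAS and GART by 0.35 ± 0.0624 and 0.29 ± 0.0484 (edgeR adjusted p between 0.000992 and 0.00534). NME2 shares 38.5% of its exonic bases with another gene of the same strand and is uncertain, and the gene that fell, named after its value was seen, was TK1. Of 15 genes of one-carbon, serine and polyamine metabolism, 6 rose and 1 fell, with a median of 0.10 (camera adjusted p = 0.0336, and an adjusted p = 0.207 with an estimated correlation). SRM and ODC1, which encode enzymes of polyamine synthesis, rose by 1.07 ± 0.103 and 0.44 ± 0.0502, MTHFD1L by 0.42 ± 0.0755 and MAT2A by 0.25 ± 0.0557 (edgeR adjusted p between 0.00013 and 0.0127). The one that fell was GLDC, named after its value was seen. Of 20 aminoacyl-tRNA synthetase genes, 6 rose and 0 fell, with a median of 0.13 (camera adjusted p = 0.0181, and an adjusted p = 0.336 with an estimated correlation). VARS1 rose by 0.46 ± 0.0544, LARS1 by 0.26 ± 0.0494, FARSA by 0.22 ± 0.0534 and TARS1 by 0.21 ± 0.054 (edgeR adjusted p between 0.000483 and 0.0213). Of 19 heat shock and chaperone genes, 9 rose and 0 fell, with a median of 0.18 (camera adjusted p = 0.00031, and an adjusted p = 0.227 with an estimated correlation). HSP90AB1 rose by 0.56 ± 0.094, the mitochondrial chaperone genes HSPD1 and HSPA9 by 0.47 ± 0.0505 and 0.40 ± 0.0583, and CCT5 by 0.31 ± 0.0603 (edgeR adjusted p between 0.00025 and 0.00754).

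Adjusted over the list alone, 12 nucleotide synthesis genes were higher and 3 lower, 6 and 1 of the one-carbon list, 8 and 1 of the synthetases, and 10 and 0 of the chaperones. The one-carbon and synthetase lists missed the threshold under library totals only (camera adjusted p = 0.0739 and 0.0738, with ranges of 0.00431 to 0.207 and 0.000645 to 0.336 over all alternatives tested with camera). The one-carbon list also missed it in limma-voom (0.0665), with GC offsets (0.0507), among genes of at least 2500 bases (0.111), without washout library 1 or 2 (0.0719 and 0.0716) and without mock washout library 1 or 3 (0.0513 and 0.0751). The synthetase list missed it without washout library 1 or 2 (0.0719 and 0.0774). The calls of FARSA, TARS1 and MAT2A were each lost without washout library 2 or any 1 of the mock washout libraries (highest edgeR adjusted p = 0.0899, 0.118 and 0.0679), that of LARS1 without mock washout library 3 (0.0523) and that of CCT5 without mock washout library 1 (0.0559). FARSA and TARS1 also lost theirs under library totals only (0.0789 and 0.0611), and FARSA with gene-length offsets (0.0626). Without washout library 2, then mock washout libraries 1, 2 and 3, the genes that rose numbered 6, 5, 7 and 4 for nucleotide synthesis, 3, 3, 3 and 3 for the one-carbon list, 2, 2, 2 and 1 for the synthetases, and 5, 3, 6 and 5 for the chaperones.

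Genes of cholesterol synthesis and uptake were lower in washout: 14 of 24 fell and 0 rose, with a median of -0.21 (camera adjusted p = 9.68e-07, and an adjusted p = 0.207 with an estimated correlation). EBP and SC5D, which encode enzymes late in the pathway, changed by -0.44 ± 0.0767 and -0.30 ± 0.0605, the sterol carrier gene STARD4 by -0.40 ± 0.0641 and the early enzyme gene HMGCS1 by -0.31 ± 0.058 (edgeR adjusted p between 0.00317 and 0.00862). Of 19 FOXO target and T-cell quiescence genes, 7 fell and 2 rose, with a median of -0.18 (camera adjusted p = 0.00607, and an adjusted p = 0.134 with an estimated correlation). CCR7, a chemokine receptor gene of naive T cells, fell from 9.64 ± 0.789 to 4.58 ± 0.541 CPM, a change of -1.07 ± 0.115. CCNG2 changed by -0.63 ± 0.0694, TSC22D3 by -0.55 ± 0.09 and SESN1 by -0.43 ± 0.0639 (edgeR adjusted p between 0.000266 and 0.00331). BCL2L11, a pro-apoptotic gene, and GADD45A, a stress response gene, were the pair that rose, named after their values were seen. Of 30 genes of the G1/S transition and DNA replication, 6 fell and 0 rose, with a median of -0.10 (camera adjusted p = 0.0136, and an adjusted p = 0.227 with an estimated correlation). CCNE2, an E-type cyclin gene, changed by -0.33 ± 0.0512, E2F2 by -0.26 ± 0.0711, and the replication genes PCNA and CDC6 by -0.22 ± 0.0604 and -0.22 ± 0.0568 (edgeR adjusted p between 0.0024 and 0.0282). Of 29 genes of the G2/M transition and mitosis, 7 fell and 3 rose, with a median of -0.12 (camera adjusted p = 0.0208, and an adjusted p = 0.415 with an estimated correlation). UBE2C changed by -0.29 ± 0.0655, DLGAP5 by -0.27 ± 0.0752, TTK by -0.25 ± 0.0698 and AURKA by -0.23 ± 0.0624 (edgeR adjusted p between 0.0138 and 0.0319), and the 3 that rose, named after their values were seen, were BUB1B, CENPF and MKI67.

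Adjusted over the list alone, 18 cholesterol genes were lower and 0 higher, 7 FOXO targets lower and 3 higher, 10 G1/S genes lower and 2 higher, and 10 G2/M genes lower and 4 higher. Among genes of at least 2500 bases the G1/S and G2/M lists missed the threshold (camera adjusted p = 0.112 and 0.407, with ranges of 0.000167 to 0.227 and 0.000453 to 0.415 over all alternatives tested with camera), and the G2/M list also missed it without mock washout library 2 (0.0598). The calls of CDC6, E2F2, PCNA, DLGAP5, AURKA and TTK were each lost without washout library 2 or any 1 of the mock washout libraries (highest edgeR adjusted p between 0.104 and 0.128), UBE2C without any 1 of the mock washout libraries (up to 0.0606) and SC5D without mock washout library 1 (0.0506). Without washout library 2, then mock washout libraries 1, 2 and 3, the genes that fell numbered 6, 3, 5 and 4 for cholesterol, 1, 1, 1 and 1 for G1/S, and 1, 0, 0 and 1 for G2/M, and without washout library 1 the last list had 13.

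**Figure D4:**
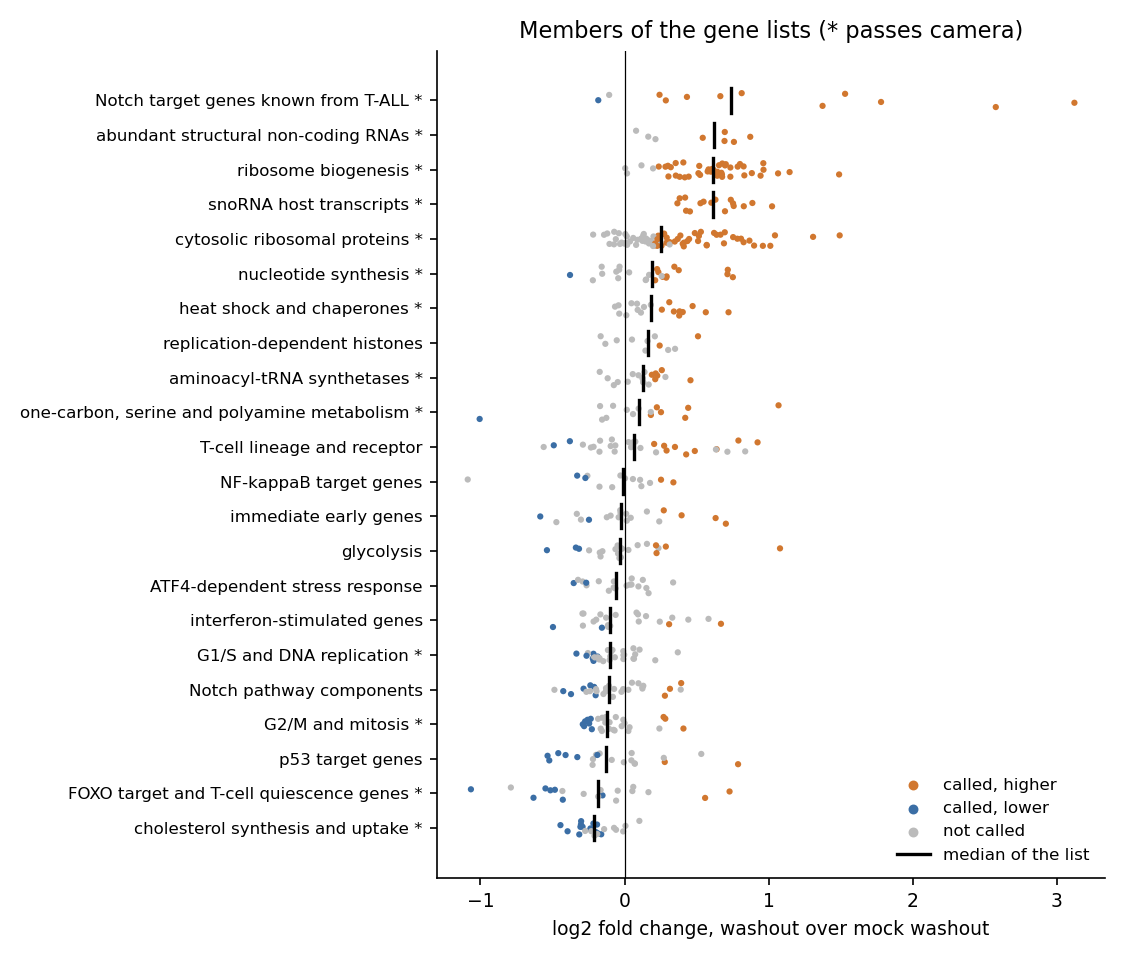
Log2 fold change of washout over mock washout for every tested member of the 22 lists tested, with one point per gene (orange called higher, blue called lower, grey not called), a black bar for the median of the list and a star for lists that pass camera. The median is highest for Notch targets at 0.74, followed by structural RNAs, ribosome biogenesis genes and snoRNA host transcripts at 0.62 each, and lowest for cholesterol genes at -0.21.

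The remaining lists did not pass camera. Of 30 T-cell lineage and receptor genes, 9 rose and 2 fell, with a median of 0.07 (camera adjusted p = 0.0522). CD7, a surface marker gene of T cells, rose by 0.92 ± 0.0726 and CD1B, an antigen-presenting molecule gene of thymocytes, by 0.79 ± 0.0533 (edgeR adjusted p = 3.95e-05 and 1.45e-05), while TOX, named after its value was seen, was among those that fell. Of 29 components of the Notch pathway outside the target list, 6 fell and 3 rose, with a median of -0.11 (camera adjusted p = 0.0572). MAML2, a coactivator gene, changed by -0.43 ± 0.0649 and APH1B, a gamma-secretase subunit gene, by -0.37 ± 0.0588 (edgeR adjusted p = 0.00236 and 0.00285), and SPEN and CIR1, named after their values were seen, were among those that rose. Of 20 p53 target genes, 6 fell and 2 rose, with a median of -0.13 (camera adjusted p = 0.0573). AEN, an apoptosis nuclease gene, rose by 0.79 ± 0.0814 and TP53INP1 changed by -0.53 ± 0.0692 (edgeR adjusted p = 0.000204 and 0.000875), and XPC also rose, named after its value was seen. Of 22 glycolysis genes, 4 rose and 3 fell, with a median of -0.03 while the mean of 0.01 and camera pointed up (camera adjusted p = 0.691). HK2, a hexokinase gene, rose by 1.08 ± 0.059 and SLC2A3, a glucose transporter gene, changed by -0.54 ± 0.075 (edgeR adjusted p = 3.51e-06 and 0.00137). PFKP, LDHA and ENO1 also rose and ENO2 and GAPDH also fell, named after their values were seen.

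Of 19 immediate early genes, 4 rose and 2 fell, with a median of -0.03 while the mean of 0.01 and camera pointed up (camera adjusted p = 0.691). EGR1, a growth response factor gene, rose by 0.63 ± 0.0877 and BTG2, an antiproliferative gene, by 0.27 ± 0.0488 (edgeR adjusted p = 0.00134 and 0.00517). DUSP2 and ZFP36 also rose and JUND and IER3 fell, named after their values were seen. Of 23 interferon-stimulated genes, 2 rose, XAF1 at 0.31 ± 0.0674 and IFITM1 at 0.67 ± 0.184 (edgeR adjusted p = 0.012 and 0.0283), and IFI6, named after its value was seen, was among the 2 that fell. This list had a median of -0.10 and a mean of 0.02, and camera pointed down (adjusted p = 0.529). Of 14 targets of NF-kappaB, 2 rose and 2 fell, with a median of -0.01 (camera adjusted p = 0.529). TNFAIP3, an inhibitor of the pathway, rose by 0.25 ± 0.0559 and CD83 changed by -0.27 ± 0.0648 (edgeR adjusted p = 0.0127 and 0.017), and TNF rose and BIRC3 fell, named after their values were seen. Of 19 genes of the ATF4 stress response, PCK2 and VLDLR fell, at -0.35 ± 0.101 and -0.27 ± 0.0799 (edgeR adjusted p = 0.0326 and 0.0385), with a list median of -0.06 (camera adjusted p = 0.379). Of 11 replication-dependent histone genes, H1-5 and H2AC11 rose, at 0.51 ± 0.148 and 0.24 ± 0.0763 (edgeR adjusted p = 0.0342 and 0.0441), with a list median of 0.16 (camera adjusted p = 0.288). For IFITM1, 32.5% of the exonic bases overlap another gene of the same strand, and its level is uncertain.

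Adjusted over the list alone, the counts of higher and lower genes were 11 and 6 for T-cell genes, 3 and 7 for Notch components, 2 and 7 for p53 targets, and 4 and 3 for glycolysis. They were 6 and 2 for immediate early genes, 3 and 3 for interferon-stimulated genes, 2 and 4 for NF-kappaB targets, 0 and 0 for the ATF4 list, and 3 and 1 for histones. The T-cell list passed with upper-quartile factors, without an abundance filter, without washout library 3 and without mock washout library 2 (camera adjusted p = 0.0446, 0.026, 0.00196 and 0.0305, range over all alternatives tested with camera 0.00196 to 0.506). The p53 list passed without washout library 2, without mock washout library 2 and without an abundance filter (0.0419, 0.0393 and 0.0138), and the Notch components without mock washout library 1 and without an abundance filter (0.0352 and 0.0259). Over all alternatives tested with camera these lists ranged from 0.0138 to 0.296 and from 0.0259 to 0.229. In fry, which tests whether a list's genes move one way and does not compare them with other genes, the T-cell, p53 and Notch component lists passed (fry adjusted p = 0.0452, 0.0386 and 0.00524). With the replicate number as a block, the T-cell and p53 lists passed camera as well. The histone list turned to medians of -0.01 and -0.03 with gene-length and transcript-length offsets, and H1-5, H2AC11 and VLDLR lost their calls with transcript-length or gene-length offsets (highest edgeR adjusted p = 0.085, 0.0675 and 0.0578). The calls of TNFAIP3, PCK2, VLDLR, IFITM1, H1-5 and H2AC11 were each lost without washout library 2 or any 1 of the mock washout libraries (highest edgeR adjusted p between 0.0795 and 0.174). The call of CD83 was lost without washout library 2 or mock washout library 1 or 3 (up to 0.0727) and that of XAF1 without mock washout library 1 or 2 (up to 0.0755). In DESeq2, IFITM1 and H1-5 missed the threshold (adjusted p = 0.0688 and 0.0817), and H2AC11 missed it in edgeR under library totals only and with GC offsets (adjusted p = 0.0775 and 0.0536). Without washout library 2, then mock washout libraries 1, 2 and 3, the genes that rose numbered 5, 5, 6 and 6 for T-cell genes, 1, 1, 3 and 1 for glycolysis, and 2, 2, 2 and 2 for immediate early genes, and the Notch components that fell numbered 2, 2, 2 and 2. In the same order the interferon-stimulated genes that rose numbered 1, 0, 0 and 1, and 0 histone genes rose, while without washout library 1 the histone genes that rose numbered 7.

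Markers of other cell types differed in level. The 12 breast epithelial markers together held 3 to 15 counts per library and the 12 myeloid markers 5 to 12, against 527 to 1031 for the 12 fibroblast and stromal markers and 6202 to 9641 for the 12 B-cell markers. Of the B-cell markers, CD79A, CD79B, BLK and EBF1 were tested, and EBF1, a transcription factor gene of the B lineage, fell from 68.7 ± 2.38 to 51.1 ± 2.3 CPM, a change of -0.43 ± 0.0573 (edgeR adjusted p = 0.00113). Of the fibroblast and stromal markers, 3 were tested and PDGFRB, a growth factor receptor gene, rose by 1.16 ± 0.0774, from 12.5 ± 0.893 to 28 ± 1.26 CPM (edgeR adjusted p = 1.4e-05). The mitochondrially encoded mRNAs were not measurable, since the count tables hold 0 genes of the mitochondrial chromosome.

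Genes that rose lay beside each other in the genome more often than drawn genes did. Among tested genes on the same chromosome with bodies at most 100 kb apart and not overlapping, 433 pairs had both members higher, against a mean of 334 pairs (middle 95% of draws 294 to 377) in 10000 draws of as many genes matched on expression. The ratio was 1.3, and the one-sided permutation p of 0.0001 is the smallest that the draws can give. For genes that fell, the 245 pairs were 1.04 times the mean of the draws (one-sided permutation p = 0.309). Of the 433 pairs, 69 shared a symbol stem, and 28 of these came from 8 immunoglobulin heavy chain segments (IGHV) on chromosome 14 and 9 from the 7 GIMAP genes on chromosome 7, both singled out after their values were seen. Without mock washout library 1 the ratio for higher genes was 2.08 from 61 pairs, and without mock washout library 3 it was 2.2 from 97 pairs. Without pairs of genes that share a symbol stem it was 1.16 (one-sided permutation p = 0.0098), and among named protein-coding genes of different stems, with draws from those genes, it was 1.15 from 230 pairs (one-sided permutation p = 0.0322). Genes are not independent replicates, so these values describe the present libraries.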

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

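The newer edgeR fit, the offsets for GC content and transcript length, the runs without the 20 most abundant genes or genes under 2500 bases, and 5 counts of neighbouring pairs were chosen after the data were seen. The older edgeR fit is the default and was not run separately. Calls of the Notch target and ribosome biogenesis lists held under all alternatives run, with medians of 0.69 to 1.00 and 0.55 to 0.68, and neighbouring pairs of higher genes stayed past 0.05 with ratios of 1.13 to 2.2. With 1 library left out, called genes ranged from 791 to 4600, higher from 479 to 2361, lower from 312 to 2239, genes at least 2-fold from 87 to 354, those higher from 85 to 331 and those lower from 2 to 23, and 30 of 100 named genes lost their call at least once. Fewer libraries lower the power, but 4600 genes without washout library 1 exceed the 3015 of all libraries, and the cause was not tested. Genes at least 2-fold (higher and lower) numbered 119 (116 and 3) in DESeq2, 115 (113 and 2) with a CPM of at least 1, and 75 (69 and 6) among genes of at least 2500 bases, where fewer genes are tested. Higher and lower ones numbered 113 and 20 with gene-length offsets and 121 and 20 with transcript-length offsets, and 22 were lower without a filter; the cause was not tested. A threshold of 0.01 left 820 genes (515 higher, 305 lower), 77 at least 2-fold (75 and 2). With an estimated correlation 2 lists passed in place of 13, where each list's own correlation takes the place of the preset 0.01. In fry 16 lists passed, 10 up and 6 down; fry tests each list on its own and not against other genes. The histone median turned to -0.0117 and -0.0322 with gene-length and transcript-length offsets, the NF-kappaB median to 0.0566 among genes of at least 2500 bases, and the glycolysis list to a camera direction of down with a median of -0.0639 without washout library 2 (with 1 library left out its median ranged from -0.0639 to 0.00152); the cause was not tested. Few or no counts limit what can be said of the untested Notch targets, which reached at most 11 counts in a library (HEY1).

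With the replicate number as a block, 3975 genes were called, and with the block and gene-length offsets 25 genes at least 2-fold were lower and the histone median was -0.00904. The block took the T-cell and p53 lists past the threshold (camera adjusted p = 0.0482 and 0.0493) and changed no other list or named gene. Deviations of same-numbered libraries correlated at 0.119, 0.0596 and 0.0913, not all above 0.1, so the numbers are not taken to pair the samples; each library did correlate best with its own number, a hint from the data and not the design.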

Other observations

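The tests of gene families, the genes around MYC, the comparisons with lists matched on transcript length, the use of the planned run without washout library 3 as a test of ribosomal protein genes, the shares among 2-fold changes and the other splits of the libraries were chosen after the result was seen; the counts of neighbouring pairs under other conditions and the test of genes near Notch targets were added after the data were seen but before their own results. The counts of pairs among protein-coding genes and away from Notch targets were added after the other counts were known, and the comparison of pairs and of Notch target neighbours with the middle 95% of draws was set after their values were seen, because a one-sided 0.05 is the looser bound. The matched lists were redrawn once, without the lists' own members, after the first percentiles were seen.

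Among 332 families of genes sharing a symbol stem, 20 passed camera, 15 up and 5 down, and none passed with an estimated correlation. With transcript-length offsets 14 of the 332 passed, not all of them among the 20. CCDC, FRMD and MYO passed only with those offsets (camera adjusted p = 0.0286, 0.0147 and 0.0286). In the main fit only 1 of 5 FRMD genes rose, FRMD4A at 2.19, and 1 of 11 MYO genes, MYO7B at 2.52. In each of these 2 families 1 gene fell, and the medians with offsets were 0.01 and 0.04. MRPL, RPS, KLHL, RAB, MRPS, TIMM, SLC, KCTD and EXOSC lost their call there (camera adjusted p from 0.0513 for RAB to 0.334 for RPS). All 7 tested GIMAP genes, GTPases of lymphocytes, rose with a median of 1.36 (camera adjusted p = 6.98e-31, and an adjusted p = 0.0799 with an estimated correlation). Their changes run from GIMAP5 at 1.74 ± 0.0777 to GIMAP6 at 0.81 ± 0.0503, and GIMAP4 stood at only 0.531 ± 0.144 CPM in washout. Of 15 genes with the stem TRMT, 11 rose, with a median of 0.33 (camera adjusted p = 0.00046), and of 5 with the stem PUS, 3 rose, PUS7 at 1.02 ± 0.0947, PUS1 at 0.92 ± 0.0871 and PUS3 at 0.43 ± 0.0813 (camera adjusted p = 0.00135). Both lost the call at an adjusted p = 0.764 with an estimated correlation. The stems ELP, NSUN and ALKBH, named after their values were seen, did not pass (camera adjusted p = 0.373, 0.406 and 0.745), and 0 of 6, 1 of 5 and 2 of 8 genes rose. Of 13 genes with the stem PIK, mostly phosphoinositide 3-kinase genes, 6 fell and 0 rose, with a median of -0.18 (camera adjusted p = 0.000626, and an adjusted p = 0.764 with an estimated correlation). PIK3R5 changed by -0.66 ± 0.065, PIK3IP1 by -0.51 ± 0.117 and PIK3CG by -0.36 ± 0.0766.

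Around MYC, within 2.5 Mb, the unnamed gene ENSG00000250400 (chromosome 8, 130228713 to 130253496, GRCh37), 1.48 Mb past the end of MYC, rose by 1.31 ± 0.091, from 5.75 ± 0.125 to 14.3 ± 1.07 CPM (edgeR adjusted p = 1.79e-05). LINC00861, 1.82 Mb before the end of MYC, rose by 0.85 ± 0.159 (edgeR adjusted p = 0.0062). A snoRNA gene of low level also rose, by 1.21 ± 0.367 (edgeR adjusted p = 0.0394). PVT1 and CCDC26, also past the end of MYC, had values of 0.35 ± 0.132 and 0.17 ± 0.116 that did not pass (edgeR adjusted p = 0.0781 and 0.301). These genes were singled out after their values were seen.

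Ribosomal protein genes, snoRNA host transcripts and ribosome biogenesis genes were higher in washout while short transcripts were higher as a class. Among 10000 random lists matched on expression and transcript length, the medians of the 3 lists lay at percentiles 99.99, 100 and 100. Random genes were drawn independently of each other, so the percentiles are too extreme for lists of correlated genes. Biogenesis genes kept their call with an estimated correlation (camera adjusted p = 0.0362), which argues against a library difference along transcript length as their whole cause. Ribosomal protein genes and host transcripts lost theirs (camera adjusted p = 0.263 and 0.134), so for them the percentiles cannot decide. Without washout library 3 the ribosomal protein median was 0.203 in place of 0.25, which argues against that library alone. At least a part of the ribosomal protein change may come from transcript length, since offsets for it left a median of 0.10. With those offsets the 40 genes of the stem RPS, some of them outside the list, went from a median of 0.21 to 0.03. They lost their call (camera adjusted p = 0.334). The 47 genes of the stem RPL went from 0.31 to 0.16 and kept theirs (camera adjusted p = 0.00393). For ribosome biogenesis genes the median was 0.65 with those offsets against 0.62 without, and the release of Notch signalling, in which the groups differ, stays open as an untested explanation.

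Among lists matched in the same way, the one-carbon and G1/S medians of 0.10 and -0.10 lay at percentiles 95.18 and 6.51, inside the middle 95% of the random lists, although both lists passed camera. The histones, which did not pass, lay at percentile 58.02 and the structural RNAs at 97.93, just above that middle range. The p53 targets, which did not pass camera (adjusted p = 0.0573), lay at percentile 1.89, just below it.

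Of the genes changed at least 2-fold, 94.9% were higher. The share was 98.3% with a CPM of at least 1 in 3 libraries and 85.8% with transcript-length offsets. These values argue against few counts and transcript length as the whole cause. Over 3 other scalings the share was 92.7% at the lowest. That cannot decide on scaling, because these scalings move the changes too little. With library totals only, the median change of all genes tested was -0.0372 in place of 0.0159. Decay of existing mRNA within 5 h may limit how far a transcript falls, which was not tested.

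Genes that rose lay beside each other 1.3 times as often as drawn genes. Without same-strand pairs within 10 kb the ratio was 1.27, and against draws matched also on exon length 1.21 (1.206). These values argue against read-through within 10 kb and against shared length, each as the whole cause. Read-through over longer distances stays open, because same-strand pairs farther apart were kept, such as IGHV3-32 and IGHV3-37 with a gap of 40070 bases. Copies in tandem families stay open: without pairs of the same symbol stem the ratio was 1.16 (1.159), but among named protein-coding genes of different stems, which also leaves out unnamed histone genes and pseudogenes, it was 1.15 (1.152, one-sided permutation p = 0.0322), and the 230 pairs lay inside the middle 95% of the draws, 170 to 232. Whether genes near Notch targets rise with them stays open too. The 79 tested genes within 500 kb of the 10 higher targets had a median of 0.10. This lay at percentile 97.45 of 2000 random sets (97.0 with transcript-length offsets), past a one-sided 95 but inside the middle 95%. Of the 79, 14 rose (17.7%, against 11.5% of all genes tested), such as SLC6A20 at 1.62 ± 0.145 and CD55 at 1.06 ± 0.196. Another 5 fell, such as GP5 at -0.54 ± 0.144 and ILVBL at -0.30 ± 0.0896. Levels were low for SLC6A20, CD55 and GP5, with mean log2 CPM of 1.99, 0.95 and 1.62, against 3.94 for ILVBL. Without the 10 targets and their neighbours, 1598 of the 1623 higher genes and 417 of the 433 pairs remained, at a ratio of 1.28 (1.279). So few pairs lie near the listed targets that this argues against them as the whole cause. Genes near responsive genes outside the list were kept, and their part was not tested.

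Of the 10 splits of the 6 libraries into 3 and 3, 1, the real split, called as many genes, 3015, and the highest other count was 0. With 10 splits a share under 0.05 cannot be reached.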
